A study of Arabidopsis thaliana with 7 samples.

How the data were processed

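RNA from whole seedlings of Arabidopsis thaliana, accession Columbia-0, was measured on 7 single-colour Agilent oligonucleotide arrays, 4 from 35S:MYB106VP16 plants and 3 from wild type. Per the labels' protocols, plants were 3 weeks old and grew on MS agar with 1% sucrose at 23 °C in cycles of 16 h light and 8 h dark, and 1 µg of total RNA was labelled with Cy3. The labels tell of plants sharing a plate, several of which went into an RNA extraction, and nothing in them says that the replicates came from separately grown batches. The p-values below therefore measure only the spread between these samples, which may be technical.

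Per the file headers, the authors extracted spot intensity with Agilent Feature Extraction 9.1.3.1, which subtracted background, removed spatial trends and merged a pair of scans, and replaced signals that could not be told from background by small positive values. The deposited flags for spots well above background, saturated spots and outlier spots were used as given (other columns were not analysed here). The authors' deposited series table holds, on a linear intensity scale with no centring, the same processed signals divided by 1 constant per group, 1042.5 for the transgenic arrays and 1237.6 for wild type. Those constants differ by 0.25 on the log2 scale, while the arrays' own 75th percentiles differ by 0.04 between the groups. How the constants were chosen is not given in the sources used here. The column medians of that table lay between 0.331 and 0.438, and it served as an alternative only.

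Each array had 45220 spots, of which 43803 were not controls, and these made up 43603 probes. For the main values, spots flagged as outliers were removed, replicate spots of a probe were averaged, and log2 of the processed signal was taken relative to the 75th percentile of the array. No processed signal was at or below 0, so no floor was needed, and no spot was saturated. The 75th percentile signal was 2213 to 2858 on the transgenic arrays and 2492 to 2677 on the wild-type arrays, and 73.5% to 76.3% of probes were well above background. The number of arrays limits the precision.

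The files name probes by RefSeq accession only. Without versions, 34185 of 36022 such probes matched the RefSeq table of assembly TAIR10.1, which gave 25347 genes, 6874 of them with several probes; 9418 probes stayed unnamed. No coordinates are given because the files name no genome build. A gene was represented by its probe with the highest mean over all 7 arrays, and tested where that probe was well above background on at least 3 arrays, which left 20509 genes. Among 6161 genes with several such probes, 323 had probes called in opposite directions; KCS5, KCS20, DEK1, PAL1, TT19 and LHCB2.1 were the listed genes among them. Probe sequences were not used here, so signal shared between close paralogs could not be assessed.

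Genes were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Calls of at least 2-fold are given beside it. Where a gene was not well above background on any array of a group, its fold is a bound, the bright group's mean against the higher of the dim probe's own signal and the lowest signal well above background on each array, and is written as "at least". The 18 gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. The 24 gene families, picked by patterns in gene symbols and synonyms because the sources used here pair no descriptions with the probes, were tested with Fisher's exact test, two-sided and adjusted over 48 tests. The genes named are MYB106 and MYB16; the 10 largest rises and 10 largest falls among called genes that have a symbol, do not overlap between groups and are well above background on every array of at least 1 group; the 4 called members of each cuticle list and the 2 of each other list with the largest absolute change, filled up to 2 by smallest p. Any other gene named was chosen after its values were seen. The lists, the families, this rule and the other settings listed next, apart from those said to be added, were fixed before the data were examined. Another 7 lists were written after the first results were seen, for the tests of the closing section.

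On simulated arrays with the means and spreads of 20479 genes, in which 200 genes were changed, the genotype comparison recovered 4% of genes changed 1.25-fold, 48% of those changed 1.5-fold, 90% at 2-fold and 98% at 4-fold (50 genes each), with 9 false calls. Many more genes differed in the data, and no slide effect or correlation between genes was simulated. These rates therefore need not hold for the real comparison. The alternatives were normexp background correction with an offset of 50 on the median spot and local background signals (the files hold no mean signal), quantile and median scaling, the authors' series table, no filter and a stricter filter on dim probes, the mean over a gene's probes, a trended and robust variance, array weights, the replicate number as a block, and leaving out each array. Added after seeing the data were a test against 1.5-fold, all probes as features, genes with a symbol as the background for families, and scaling to spike-in transcripts.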

Results

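The arrays compared whole seedlings that carried 35S:MYB106VP16 with wild-type seedlings of the same accession. MYB106 (AT3G01140) is a MIXTA-like MYB transcription factor of the epidermis, here fused to the VP16 activation domain and driven by the 35S promoter of cauliflower mosaic virus. There was 1 comparison, 4 transgenic against 3 wild-type arrays, and it asks which transcripts change when this activator is expressed throughout the plant. All transgenic arrays lay on 1 slide and all wild-type arrays on another, scanned separately, so batch and group cannot be told apart.

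MYB106 was the gene with the largest rise named here. Its signal was 52.1-fold higher in 35S:MYB106VP16 by its brighter probe (log2 5.70 ± 0.22 SE; limma adjusted p = 2.74e-05) and 36.8-fold higher by the other, and each transgenic array exceeded each wild-type array. MYB16 (AT5G15310), its closest homolog and also a regulator of epidermal cell shape and cuticle, was 2.35-fold lower (log2 -1.23 ± 0.22 SE; limma adjusted p = 0.00287). SHN1 (AT1G15360), an ERF factor that activates cuticle genes, was 7.30-fold higher, and was well above background on 2 of 3 wild-type arrays.

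**Figure D1:**
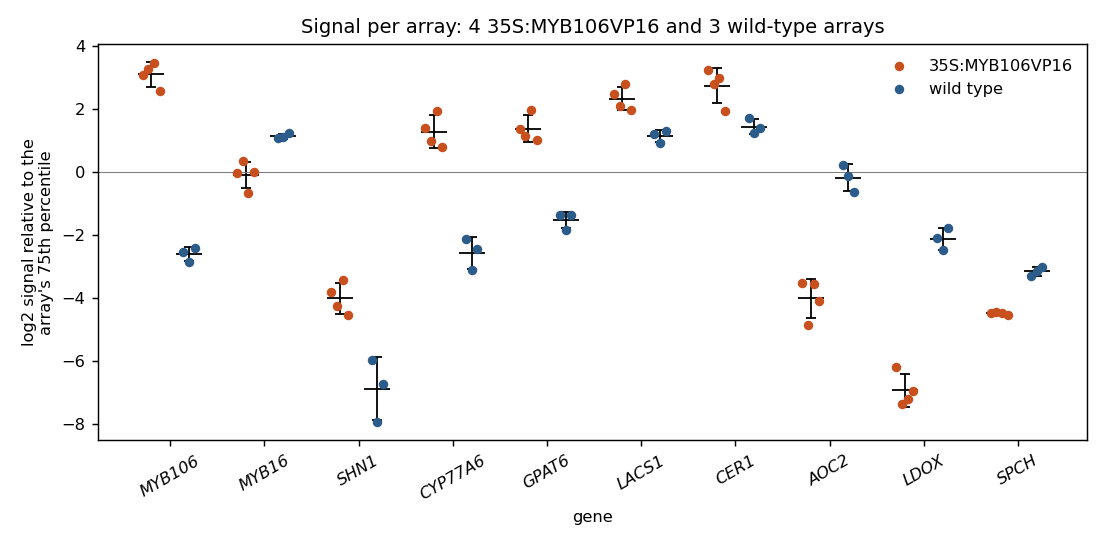
Log2 signal relative to the 75th percentile of each array for 10 named genes; each point is 1 array, orange for 35S:MYB106VP16 and blue for wild type, and black bars give mean ± SD. MYB106 had a mean of 3.11 in 35S:MYB106VP16 and -2.60 in wild type, and MYB16 had -0.09 and 1.14.

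The transcriptomes differed widely. Of 20509 genes tested with limma, 5766 were higher and 5093 lower in 35S:MYB106VP16, 52.9% in all, and 1183 were higher and 971 lower by at least 2-fold. The median absolute log2 change of the called genes was 0.58. The groups did not overlap for 57.6% of genes, against 5.71% by chance. Arrays of the same group correlated across genes at 0.988 to 0.995, and arrays of different groups at 0.955 to 0.966; genes are not independent replicates.

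The direction of small changes rested on the scaling. Of the genes called, 53.1% were higher with 75th percentile scaling, 66.6% with median scaling, 76.2% with the authors' series table and 8.61% when the arrays were scaled to the bright spike-in transcripts. The median log2 change of all genes was 0.02, 0.14, 0.23 and -0.54 in the same order, and every change below reads against the first of these. The 7 bright spike-in transcripts, RNAs added at labelling that are not from the plant, were themselves higher on the transgenic slide by 0.20 to 0.88 on the log2 scale, with a median of 0.56. Whether the spike-in mix was added in equal amounts to both sets of samples is not given in the sources used here, and counts with spike-in scaling hold only if it was. Changes above 0.88 in absolute value, the largest spike-in difference, were found in 2750 called genes. That cut counts rises and falls alike, although all bright spike-ins moved upward.

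**Figure D2:**
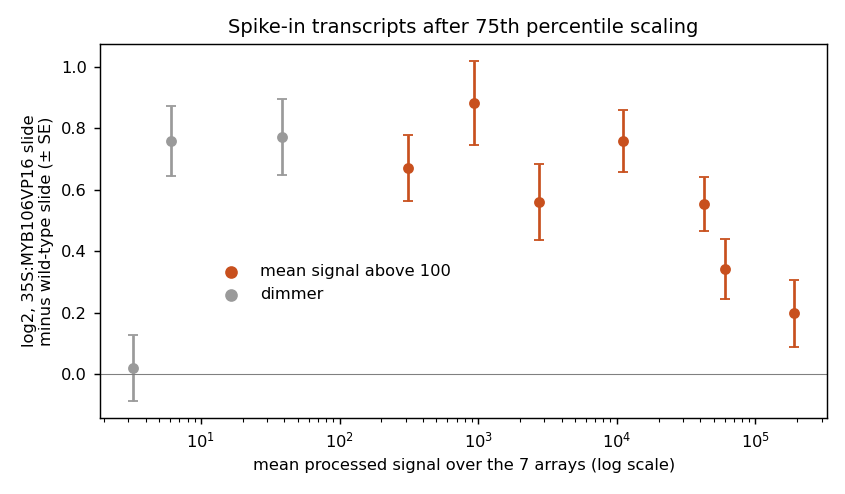
Log2 difference between the slides (y axis, 35S:MYB106VP16 minus wild type, with the SE from arrays within slides) of each of 10 spike-in transcripts against its mean processed signal (x axis, log scale). The 7 with a mean signal above 100 (orange) lay between 0.20 and 0.88.

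SAG13, a senescence-associated dehydrogenase, was 43.9-fold higher, with 2 of 3 wild-type arrays well above background, and the size of its rise is uncertain. It was 21.8-fold without wild type replicate 3, 89.4-fold without wild type replicate 2 and 27.0-fold without 35S:MYB106VP16 replicate 4, and SAG13 stood at log2 2.8 against 5.5 with normexp background subtraction. Smaller folds with normexp were not particular to SAG13: genes higher by at least 2-fold went from 1183 to 658. CLPB2, a ClpB chaperone, was at least 13.2-fold higher, CYP71A13, a cytochrome P450 of camalexin synthesis, at least 11.5-fold, and AT59, a pectate lyase, at least 14.7-fold; none of these was well above background in wild type. M17, a late embryogenesis abundant protein, was 33.7-fold higher and DIR5, a dirigent protein, 29.6-fold. The defensin genes PDF1.3, PDF1.2c and PDF1.2b were 27.5-fold, 27.2-fold and 26.8-fold higher, and their close sequences could share signal on the array. Limma adjusted p of these genes ranged up to 0.00506, that of SAG13.

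LDOX, an enzyme late in anthocyanin synthesis, was 28.1-fold lower (limma adjusted p = 8.98e-05). MYB76, a regulator of aliphatic glucosinolates, was lower as well (limma adjusted p = 0.000147), but was well above background on 1 of 4 transgenic arrays, so the size of its fall, 28.7-fold as fitted, is uncertain. AT5MAT, an anthocyanin malonyltransferase that was 21.1-fold lower, was well above background on 2 of them. TPS03, a terpene synthase, was not well above background in 35S:MYB106VP16 and was at least 9.98-fold lower. FAMT, a farnesoic acid methyltransferase, was 17.0-fold lower, SWEET4, a sugar transporter, 16.7-fold, MSRB6, a methionine sulfoxide reductase, 15.5-fold, and AOC2, an allene oxide cyclase of jasmonate synthesis, 14.3-fold. 4CL8, well above background on 3 of 4 transgenic arrays, was 13.8-fold lower and COR15A, a cold-regulated chloroplast protein, 11.2-fold.

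Of 20 cutin and cuticle assembly genes, 11 rose, 3 fell and 6 were not called, with the same numbers adjusted over the list alone. CYP77A6 and GPAT6, which act in the synthesis of cutin monomers, were 14.5-fold and 7.47-fold higher, and the fatty acid hydroxylases CYP86A7 and CYP86A4 10.6-fold and 7.39-fold. BDG1, named after its value was seen, was lower (log2 -1.63). The list did not pass camera (limma, adjusted p = 0.0541; adjusted p = 0.839 with an estimated correlation). With spike-in scaling 7 members rose and 6 fell, while the list passed camera upward (limma adjusted p = 4.67e-05), as it did with normexp (0.025), the authors' series table (0.0181), no filter on dim probes (0.042) and detection on all arrays (0.0427). Spike-in scaling and the authors' series table shift the log2 change of all genes alike. The members thus gained nothing on other genes there, and passing under them is no separate support.

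Of 22 wax synthesis and export genes, 13 rose, 5 fell and 4 were not called, also when adjusted over the list alone (camera in limma, adjusted p = 0.254). WSD1, a wax ester synthase, was 9.08-fold higher, with 2 of 3 wild-type arrays well above background. CER4, an alcohol-forming reductase, was 4.45-fold higher and CER1, of alkane synthesis, 2.46-fold. LACS1, a long-chain acyl-CoA synthetase that also stands in the cutin list, was 2.28-fold higher. CER3, named after its value was seen, was lower (log2 -1.068; limma adjusted p = 0.000143). With spike-in scaling 4 members rose and 8 fell, while the list passed camera upward (limma adjusted p = 0.022). As for cutin, that scaling left the log2 changes relative to other genes as they were. Of 14 cuticle regulators, 5 rose, MYB106 itself among them, and 3 fell, also adjusted over the list alone (camera in limma, adjusted p = 0.726). SHN2, a relative of SHN1, was lower (log2 -0.998). Of 13 suberin genes 1 rose and 2 fell, the latter CYP86B1 (1.59-fold) and ASFT (1.54-fold), with equal counts adjusted over the list alone (camera in limma, adjusted p = 0.558). CYP86B1 did not pass with the authors' series table (limma adjusted p = 0.0661).

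**Figure D3:**
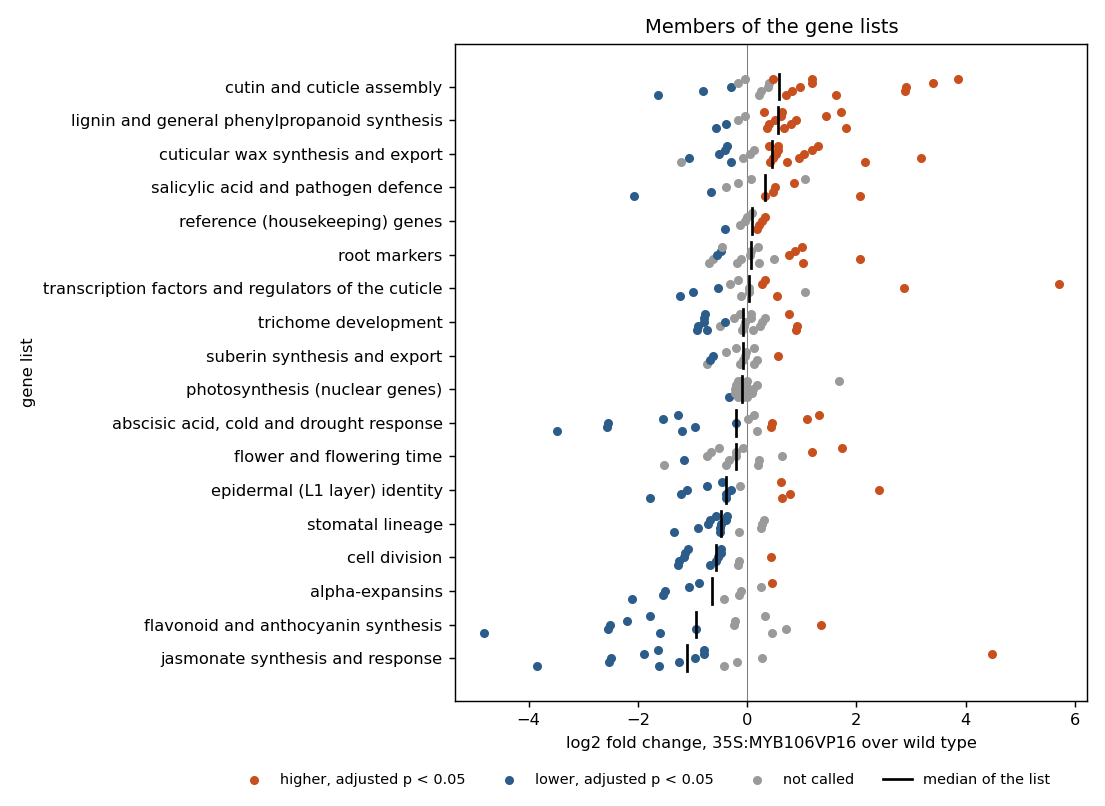
Log2 fold change of each tested member (x axis, 35S:MYB106VP16 over wild type) in the 18 gene lists (y axis, sorted by median), orange for higher, blue for lower and grey for not called; black bars mark list medians. The medians ran from -1.11 for jasmonate synthesis and response to 0.59 for cutin and cuticle assembly.

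Of 14 jasmonate synthesis and response genes, 10 fell, 1 rose and 3 were not called, also adjusted over the list alone, with a median log2 change of -1.11. AOC2 had the largest fall, and AOS and LOX2, earlier enzymes of the pathway, were 5.62-fold and 3.71-fold lower (named after their values were seen). PDF1.2, a defensin that responds to jasmonate with ethylene, was 22.4-fold higher. The list was lower by camera in limma (adjusted p = 0.00143; adjusted p = 0.775 with an estimated correlation), on 13 members with complete values.

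Genes of cell division fell. Of 13 members 10 fell, 1 rose and 2 were not called, also adjusted over the list alone, with CDKB2;2, a mitotic kinase, 2.41-fold and CYCA1;1, a cyclin, 2.38-fold lower. TSO2 (named after its value was seen), a subunit of ribonucleotide reductase, was the member that rose, 1.36-fold. The list passed camera in limma (adjusted p = 0.000496; adjusted p = 0.253 with an estimated correlation). Of 14 stomatal lineage genes 10 fell and 4 were not called, while 1 rose when adjusted over the list alone; SPCH, the factor that starts the lineage, was 2.52-fold lower and SDD1, a protease, 1.87-fold. Of 10 alpha-expansins, proteins that loosen cell walls, 5 fell and 1 rose, against 6 and 1 adjusted over the list alone, and EXPA5 and EXPA15 were 4.33-fold and 2.91-fold lower. Camera in limma gave adjusted p = 0.029 for the stomatal list and 0.0311 for expansins, each with adjusted p = 0.839 with an estimated correlation. Without 35S:MYB106VP16 replicate 3 both stood at adjusted p = 0.0638 in limma, and with spike-in scaling both at 0.105. The latter scaling shifts the log2 change of all genes alike. With the mean over a gene's probes, limma gave adjusted p = 0.0527 for the stomatal list and 0.0728 for expansins.

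Of 16 lignin and general phenylpropanoid genes 12 rose and 2 fell, also adjusted over the list alone (camera in limma, adjusted p = 0.029; adjusted p = 0.839 with an estimated correlation). OMT1, a methyltransferase, was 3.50-fold and PAL4, a phenylalanine ammonia-lyase, 3.28-fold higher. With spike-in scaling 3 members of that list rose and 4 fell, and with the mean over a gene's probes its limma adjusted p was 0.156. Of 13 flavonoid and anthocyanin genes 7 fell and 1 rose, against 7 and 3 adjusted over the list alone. DFR, which precedes LDOX, was 5.81-fold lower. That list did not pass camera in limma (adjusted p = 0.0982).

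Defence, stress and cell type lists were mixed. Of 11 salicylic acid and pathogen defence genes 5 rose and 2 fell, against 6 and 2 adjusted over the list alone; WRKY70, a defence regulator, was lower (log2 -2.07), and PR2, a glucanase well above background on 2 of 3 wild-type arrays, 4.18-fold higher (limma adjusted p = 0.0377, and 0.0504 to 0.119 without any of 5 arrays in turn, all but replicates 2 and 4 of 35S:MYB106VP16, and 0.057 with no filter on dim probes). PR1, ALD1 and NIMIN1, also on the salicylic acid list, were not tested, since their probes were not well above background on at least 3 arrays. Of 15 abscisic acid, cold and drought genes 8 fell and 4 rose, also adjusted over the list alone, COR15A and KIN1 (5.94-fold) by the most. KIN1 did not pass with the mean over its probes (log2 -0.94; limma adjusted p = 0.0516). Of 13 epidermal identity genes 8 fell and 4 rose, also adjusted over the list alone; HDG5, a homeodomain factor, was 3.42-fold lower and LTP2, a lipid transfer protein, 5.35-fold higher. Of 22 trichome genes 7 fell and 3 rose, also adjusted over the list alone, with ETC2 1.89-fold lower and CPL3 1.89-fold higher, both single-repeat MYB proteins. CPL3 did not pass with the mean over its probes (limma adjusted p = 0.0522) or with spike-in scaling (0.18). Camera in limma gave adjusted p = 0.668 for the salicylic acid list, 0.288 for both the abscisic acid and epidermal lists and 0.515 for the trichome list.

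Among root markers 5 of 17 rose and 2 fell, against 5 and 1 adjusted over the list alone; PRP3 (4.16-fold) and EXPA7 (2.03-fold), both of root hairs, rose most by absolute change, though EXPA7 did not pass with spike-in scaling (limma adjusted p = 0.0902). Of 15 flower and flowering time genes 2 rose, FT (3.35-fold), which promotes flowering, and PI (2.26-fold), and 1 fell, against 1 and 1 adjusted over the list alone. FT had a limma adjusted p of 0.0245, which lay between 0.0558 and 0.0709 without any of 6 arrays in turn, all but replicate 2 of 35S:MYB106VP16. Of 20 nuclear photosynthesis genes 1 fell, LHCA2 (log2 -0.32), and none was called adjusted over the list alone. LHCA2 did not pass with normexp (limma adjusted p = 0.0569) or the authors' series table (0.556). LHCB2.1 was 3.22-fold higher without passing (limma adjusted p = 0.0527), and its probes were called in opposite directions. Without wild type replicate 1 it was 5.99-fold higher and passed (limma adjusted p = 0.000266), as it did at 0.0046 to 0.0439 under 6 other settings. That list had a median log2 change of -0.09 and a mean of 0.01, and camera pointed down. Of 9 reference genes 4 rose and 1 fell, also adjusted over the list alone; PP2AA3 was 1.33-fold lower, with a limma adjusted p of 0.275 in the authors' series table. EF1A was 1.26-fold higher (limma adjusted p = 0.0497), but did not pass without any of 5 arrays in turn (0.0703 to 0.176), with quantile normalization (0.0587), no filter on dim probes (0.0709) or the mean over its probes (0.593), and stood at log2 -0.23 under spike-in scaling. Camera in limma gave adjusted p = 0.668 for the root, flower and reference lists and 0.406 for photosynthesis.

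None of the 48 family tests passed Fisher's exact test after adjustment, and 6 had an unadjusted p under 0.05. The patterns found only members whose symbol or synonym names the family. They counted 8 GDSL genes, 10 lipid transfer genes and 4 chlorophyll a/b-binding genes, the last fewer than the photosynthesis list holds. The tests thus speak for the members found and not for whole families. Defensins came closest, with 6 of 7 higher (odds ratio 15.4, adjusted p = 0.0744 by Fisher's exact test) and 5 of them higher under spike-in scaling. Heat shock genes were called lower in 4 of 51 (odds ratio 0.257, adjusted p = 0.0744 by Fisher's exact test). Against genes with a symbol alone, a background added after seeing the data, these became 0.0418 and 0.0375.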

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

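Of 78 values tested in the 4 transgenic arrays, 4 had 1 array far from the other 3, and chance alone gives about 1 in 20. M17 stood at -2.01 on 35S:MYB106VP16 replicate 2, against 0.09 to 0.35 on the others, and FT at -4.40 on the same array, against -2.46 to -2.21. PI stood at -0.25 on replicate 3, against 0.36 to 0.42. The mean of the stomatal lineage list stood at -2.46 on replicate 3, against -2.12 to -2.07 on the others. All 4 are log2 signals relative to the array's 75th percentile.

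Probes without a gene name entered no comparison of genes. Of 4707 such probes tested with limma, 1634 were higher and 914 lower in 35S:MYB106VP16, 54.1% in all, and 675 were higher and 240 lower by at least 2-fold. What they detect is unknown here.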

How the results depend on the processing

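Spike-in scaling, the test against 1.5-fold, all probes as features and the named background for families were chosen after seeing the data. The slide as a block was not run, since each slide holds 1 genotype. Of 1033 results of the 58 named genes under alternatives, 994 kept their direction and side of the threshold, 31 lost their call, 7 gained one, all of them LHCB2.1, and 1 turned: EF1A stood at log2 -0.23 under spike-in scaling. The cause of the changes below was not tested, except that spike-in, median and the authors' scaling shift all genes alike by construction. The lowest signals well above background limit the folds written as bounds.

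Counts of genes higher and lower were 5766 and 5093. They became 1245 and 13215 with spike-in scaling, 794 and 713 when tested against 1.5-fold, and 8917 and 8997 over all probes, while 2277 genes were lower in the authors' series table. At 2-fold, 1183 and 971 became 658 and 563 with normexp, 1852 and 608 with the authors' table, 503 and 3959 with spike-in scaling, and 2165 and 1971 over all probes. Without single arrays the counts were 4224 to 5496 higher and 3886 to 5131 lower. Family tests past the threshold, 0 as reported, numbered 1 with median scaling, no filter on dim probes or array weights, 2 with the authors' table or the named background, 4 with the replicate block, 5 with spike-in scaling and 0 to 2 without single arrays.

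Among limma's list tests, cutin (adjusted p = 0.0541) passed with normexp (0.025), the authors' table (0.0181), no filter (0.042), detection on all arrays (0.0427), spike-in scaling (4.67e-05) and fry (0.0298), and ranged from 0.0174 to 0.0825 without single arrays. It passed without 35S:MYB106VP16 replicate 2 (0.0368), replicate 4 (0.0174) or wild type replicate 3 (0.0387). With the mean over a gene's probes the stomatal (0.0527), lignin (0.156) and expansin (0.0728) lists did not pass. With spike-in scaling the stomatal and expansin lists (both 0.105) did not pass, and without single arrays they ranged from 0.0188 to 0.0638 and from 0.0201 to 0.0638. With an estimated correlation none of the 5 called lists passed: 0.253 for cell division, 0.775 for jasmonate, and 0.839 for stomatal, lignin and expansins. Lists not called as reported passed at times: flavonoids with median scaling (0.0376), the authors' table (0.00766), fry (0.0122) and without 35S:MYB106VP16 replicate 1 (0.0396) or wild type replicate 2 (0.0495), wax with spike-in scaling (0.022) and without 35S:MYB106VP16 replicate 4 (0.0252), abscisic acid with the authors' table (0.0465) and fry (0.0143), and cuticle regulators (0.00961) and trichomes (0.0104) with fry, which does not compare a list with other genes. The regulator list includes the overexpressed MYB106 (log2 5.70). Its median log2 change was 0.03 against a mean of 0.53, and it was not tested without MYB106.

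The groups share replicate numbers, but the numbers did not pair the arrays: deviations from group means correlated at 0.178, -0.025 and -0.082 for the same numbers, and not every array correlated best with its own. The number is also the place on the slide. With the replicate block, 4594 genes were higher and 4476 lower in limma, 4 family tests passed, and the cutin (adjusted p = 0.00349), wax (0.0205) and flavonoid (0.0421) lists passed, while EF1A (0.0857), LHCA2 (0.0563) and EXPA7 (0.0541) did not.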

Other observations

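The 2 tests of scaling were chosen after their results were seen, while the lists used below were written after the first gene results and before their own values, except for MYB29, MYB76, CYP79F1 and CYP71A13. Aliphatic glucosinolate genes, whose products derive from methionine, were lower in 35S:MYB106VP16. Of 13 genes 12 fell, and of the 10 whose values had not been seen 9 fell, with a median log2 change of -1.09. BCAT4 was 3.82-fold lower, BAT5 3.05-fold and CYP83A1 2.96-fold, while MAM3 stood at log2 0.01. Those 10 genes passed camera in limma over the 7 added lists (adjusted p = 0.00203; adjusted p = 0.458 with an estimated correlation). Of 12 indole glucosinolate and camalexin genes 3 fell and 1 rose, with CYP79B3 3.19-fold lower beside the rise of CYP71A13, and the 11 without CYP71A13 did not pass (adjusted p = 0.163 in limma).

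Of 6 leaf senescence genes of an added list, 5 were tested and all of these rose, with a median log2 change of 0.80. NAP, a NAC factor of senescence, rose by log2 1.14 and WRKY53 by log2 0.80. The list passed camera in limma (adjusted p = 0.00864; adjusted p = 0.191 with an estimated correlation). These genes, like the others, were read with 75th percentile scaling. With spike-in scaling the median log2 change of all genes was -0.54 against 0.02, so these rises would be smaller. Those of SEN1 (log2 0.64) and NYE1 (log2 0.61) would nearly vanish. The list was written after the first results, which included the rise of SAG13.

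The number of genes that differed was far outside other groupings of the arrays. Of the 35 splits of the 7 arrays into 4 and 3, only 1, the real one, called as many as 10859 genes. The highest of the others called 5, but every other split mixed the groups. The real split is also the split by slide. These counts show that the arrays part along group and slide together, and cannot tell why. Chance differences between plates or batches of plants were not tested, since the replicates may be technical. A slide or labelling difference cannot be told apart from genotype, since each slide holds 1 genotype. The bright spike-in transcripts differed between slides by a median of 0.56, above the lower quartile of the called genes (0.40) and just below their median (0.58). Such a difference may account for small changes in particular, but larger ones are not cleared of it. In absolute value, 2750 called genes moved by more than any bright spike-in, yet all bright spike-ins moved upward. With spike-in scaling, rises of at least 2-fold went from 1183 to 503 and falls from 971 to 3959. Equal addition of the spike-in mix to both sets is assumed here.

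The fall of jasmonate genes came with rises of genes of the ethylene-jasmonate (ERF) branch. The median log2 change of ORA59, ERF1, PR3 and PR4 was 1.90 (95% bootstrap interval -0.12 to 2.45). A hypothesis of a higher ERF branch beside a lower MYC branch would require such a rise, but the interval takes in no change. ERF1 was 5.47-fold, PR4 4.63-fold and PR3 3.00-fold higher, while ORA59 stood at log2 -0.12. The list was written after the first results, which included the rise of PDF1.2, and is a weak test for that reason. This list did not pass camera in limma (adjusted p = 0.0521). A harvest at another time of day stays open: the morning clock list (3 of 8 higher; limma adjusted p = 0.158) exceeded the evening list (3 of 10 higher, 1 lower; limma adjusted p = 0.297) by a median of 0.11, with an interval of -0.26 to 0.95 that reaches past the bound of 0.5. LHY was 2.63-fold higher, while CCA1 (log2 0.32), PRR9, PRR7, RVE8 and LNK2 of the morning list were not called. The morning and evening list medians were both positive (0.29 and 0.18), whereas another harvest time was predicted to move them in opposite directions.

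Cell division, stomatal lineage and expansin genes may have fallen because the seedlings held a smaller share of young organs. The median of 13 young organ genes was -0.35 (95% bootstrap interval -0.69 to 0.09), and 7 fell, among them ANT (2.14-fold) and GRF1 (1.85-fold), while KNAT2 rose 1.62-fold; the list did not pass camera in limma (adjusted p = 0.0593). Quantile normalization is the only scaling here that does not shift all genes alike, so the others could not change their fall relative to other genes. Under it, the median of the 3 lists together stood at -0.46 relative to all genes (95% bootstrap interval -0.70 to -0.41). The relative fall thus did not rest on a choice between these scalings. The 3 lists were put together because they fell in these data, and the interval treats their members as independent. The stomatal and expansin lists did not pass camera in limma under spike-in scaling (both adjusted p = 0.105). None of the 3 lists passed with an estimated correlation (0.253 to 0.839). How far they fell in absolute terms does rest on the scaling, with a median of -0.50 as reported, at most -0.29 under the median, quantile and authors' scaling and -1.06 under spike-in scaling. A direct effect of the transgene on these genes was not tested and stays open.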
